A study of Mus musculus with 68 samples.

How the data were processed

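RNA was measured by sequencing in 68 libraries: complete 7F on days 0, 1, 3, 5 and 7 (2 replicates per day), 7 arms lacking 1 factor each and a GFP arm (1 library per day), 5 MEF libraries, 5 iPSC lines made with 7F, 6 made from MEFs with Y'F and 2 made from TTF with Y'F. The deposited tables hold expected counts per gene which, per the submitters' processing notes, were made with bcl2fastq, Bowtie2 and RSEM on the mouse build mm10, with versions not given in the sources used here. The expected counts were rounded to whole numbers. The tables list 54752 gene identifiers, of which 54723 matched a symbol in the GRCm38 annotation; 101 symbols were shared by more than 1 identifier, and 0.0017% of counts lay in identifiers without a symbol. Library totals were 1.9 to 29.23 M counts. The mean read or fragment length in the tables sorts the libraries into classes: 74.4 or 74.5 bases for the dropouts, 7F replicate 2, MEF 1 to 3 and all iPSC lines, 167.1 to 171.1 for 7F replicate 1, 35 or 203.1 for GFP, and 58.6 and 49.1 for MEF 4 and 5. No label says which of these are reads and which are fragments of paired reads.

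Counts were normalised with TMM, filtered with filterByExpr and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The iPSC lines and MEF were fitted together with the group as the only term. The time course used the 10 libraries labelled complete 7F with day as a factor. The GFP comparison and the dropouts used day as a factor plus the arm, so that days stand in for replicates, and a separate fit with day as a number tested whether the change per day differed between 7F and GFP. Log2 fold changes are given with the standard error, and CPM (TMM-normalised) as mean with SD. Against a group without any count a fold is given as a lower bound, with 3 counts placed over that group. Where a group held 1 to 3 counts only CPM and the adjusted p are given. Gene positions are from the GRCm38 annotation.

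Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, in 12 comparisons. The estimated correlation and fry were run beside it; the p of fry tests whether the genes of a list move, on balance, 1 way, without comparing them with other genes. The 26 lists were fixed before the data were examined: naive pluripotency (delivered factors left out), primed pluripotency, fibroblast and mesenchymal, epithelial, AP-1 family, stress kinase and inflammatory, interferon response, cell cycle, p53 and senescence, primitive endoderm, trophoblast, neural, mesoderm and cardiac, skeletal muscle, blood and macrophage, endothelial, keratinocyte, adipocyte, cartilage and bone, 2-cell-like, germ line, imprinted, glycolysis, oxidative phosphorylation, cholesterol synthesis, and sex-linked genes. A list needed 4 tested members. Of 302 list tests camera called 92, fry 107 and camera with an estimated correlation 1. Fry called 0 lists for the Mkk6 dropout, the Kdm2b dropout and 7F against Y'F lines, where camera called 7, 3 and 1. For the Nanog dropout fry called 3 and camera 7. In 24 of the 302 the median log2 fold change and the direction of camera differed in sign, and 0 of these were called.

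The genes named in the text were set by a rule: the 7 delivered factors; the 8 highest and 8 lowest log2 fold changes of a comparison (4 and 4 in a dropout) among called genes with an average log2 CPM of at least 2 whose groups did not overlap, or whose difference had the same sign on all 5 days; and the 3 members of each list with the smallest adjusted p. Symbols of the form Gm with digits or ending in Rik were left out of the highest and lowest. A gene under 2 parts of the rule counts under both, and the text leaves some out. Exceptions, chosen after their values were seen, are Gm12397 and Col1a1 in the Y'F lines. The reprogramming position is the mean log2 CPM (prior count 2) of the 500 genes with the highest log2 fold change between 7F iPSC and MEF minus that of the 500 with the lowest, delivered factors left out, scaled to 0 at the MEF mean and 1 at the 7F iPSC mean.

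Replicate numbers of the time course were checked for pairing by correlating the replicate differences of each pair of days: all 10 pairs had r over 0.1 (0.434 to 0.597, median 0.488), so the replicate block was also fitted. All replicate 1 libraries had a length of 167.1 to 171.1 bases and all replicate 2 libraries 74.5. The check therefore cannot separate pairing of cultures from the kind of library. The line numbers of the 7F and Y'F iPSC lines showed no such correlation (r from -0.132 to 0.031 for the same number and from -0.25 to 0.328 for other numbers). Across 41 pairs of replicate libraries the lowest chi-square per gene was 4.07 and r ran from 0.932 to 0.977, so none are copies of each other.

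The code was tested on simulated data in which 100 genes were changed by 2-fold and 100 by 4-fold, at the depth and spread of each comparison. Libraries were simulated independently, without any difference shared by the libraries of a series of days or of a replicate number. Where days stand in for replicates, the numbers below therefore do not measure the error of the real comparison. edgeR recovered 50 and 86 for 7F iPSC against MEF (5 unchanged genes called, of 14805 genes), 64 and 94 for Y'F against MEF (11 of 14791), 63 and 87 for 7F against Y'F lines (8 of 14792), 26 and 79 for TTF (6 of 14807), 34 and 92 for 7F against GFP (7 of 14365), and 78 to 89 and 96 to 99 for the dropouts (at most 11 of 15390). On the 4 time course days it recovered 6 to 17 of the 2-fold and 72 to 79 of the 4-fold changes (at most 7 unchanged genes called). For the difference in change per day the fold was reached on day 7, in even steps on the log2 scale. There edgeR recovered 0 of 100 at both 2-fold and 4-fold, and DESeq2 recovered 1 and 34.

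Alternatives were DESeq2 1.42.0 in place of edgeR, its size factors in place of TMM, no low-count filter, leaving out 1 library (in groups of at most 5) or 1 day, fitting only the groups compared, 7F replicate 1 or 2 alone, days 3 to 7 alone, the other 6 dropouts as the reference, MEF libraries of 1 kind, 200 genes for the position, and the block. Where 1 library was left in a group, it was assumed to vary like the other groups. The 12 comparisons with at least 3 libraries per group, which leaves out TTF and the single days, were also repeated on 50 splits of their samples. A gene count is called moved when it changes by more than 1.5 times.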

Results

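RNA sequencing was used to measure transcripts in mouse cells during and after reprogramming by 7 factors (7F), delivered to mouse embryonic fibroblasts (MEFs) with retroviruses. The factors were the AP-1 repressor Jdp2, the histone demethylase Jhdm1b (gene symbol Kdm2b), the kinase Mkk6 (gene symbol Map2k6) and the transcription factors Glis1, Nanog, Esrrb and Sall4. The 68 libraries held complete 7F (2 replicates on each of days 0, 1, 3, 5 and 7), 7 arms that each lacked 1 factor and a GFP control arm (1 library per day each). They also held 5 MEF libraries and induced pluripotent stem cell (iPSC) lines. The iPSC lines were 5 made with 7F, 6 made from MEFs with a combination that the labels call Y'F, and 2 made from cells labelled TTF with Y'F. Day 0 followed infection, so that the delivered genes were already transcribed. Library totals ran from 1.9 to 29.23 M counts (M, mega), with medians of 4.74 M for 7F replicate 1, 5.75 M for 7F replicate 2, 4.03 M for the 7F iPSC lines and 4.18 M for MEF. GFP libraries had the highest median, 19.57 M, although the GFP day 0 library held 1.9 M, and MEF 4 held 22.79 M. The dropout libraries held 3.64 to 8.69 M, the lines made from MEFs with Y'F 3.7 to 8.44 M, and the TTF lines 2.77 to 3.67 M. Nothing in the labels says whether replicates came from separate cultures, so the p-values measure the spread between these samples only.

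Each delivered gene was read first in every reprogramming library, as a check of the labels. In normalised counts (CPM), Nanog was 1.26 to 6.58 in the 5 libraries without Nanog and 469 to 3940 in the other 30 dropout libraries. Esrrb was 1.29 to 2.85 without Esrrb and 510 to 4850 in the others, and Sall4 was 1.32 to 28.5 without Sall4 and 432 to 3880 in the others. Glis1 was 0.211 to 4.19 without Glis1 against 70.7 to 413. Jdp2 was 7.35 to 37.9 without Jdp2 against 159 to 1970. Kdm2b kept a measurable level of 56.3 to 244 without Kdm2b, against 343 to 3330, and was 26.3 to 72.9 in GFP. Map2k6 was 3.57 to 19.3 without Mkk6 against 158 to 2420. The 5 libraries labelled complete 7F replicate 1 did not follow their label for this gene: Map2k6 was 8.28 to 17 there, 157 to 1480 in replicate 2 and 2.79 to 10.4 in GFP. In these 5 libraries Sall4 was 657 to 2390 and Nanog 582 to 1440. Kdm2b was 404 to 1700 in 4 of them and 197 on day 3, inside the range of the dropout. Every direction drawn from the libraries labelled complete 7F therefore rests partly on 5 libraries with Map2k6 at the level of its dropout. On the mouse genome build GRCm38 the genes lie on chromosome 12 (Jdp2, 85599027 to 85639878, and Esrrb, 86361117 to 86521628) and chromosome 5 (Kdm2b, 122870665 to 122989823). The others lie on chromosome 11 (Map2k6, 110399122 to 110525522), chromosome 4 (Glis1, 107434591 to 107635061), chromosome 6 (Nanog, 122707489 to 122714633) and chromosome 2 (Sall4, 168748332 to 168767943). Counts of a delivered gene add the vector's transcripts to those of the cell's own copy.

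**Figure D1:**
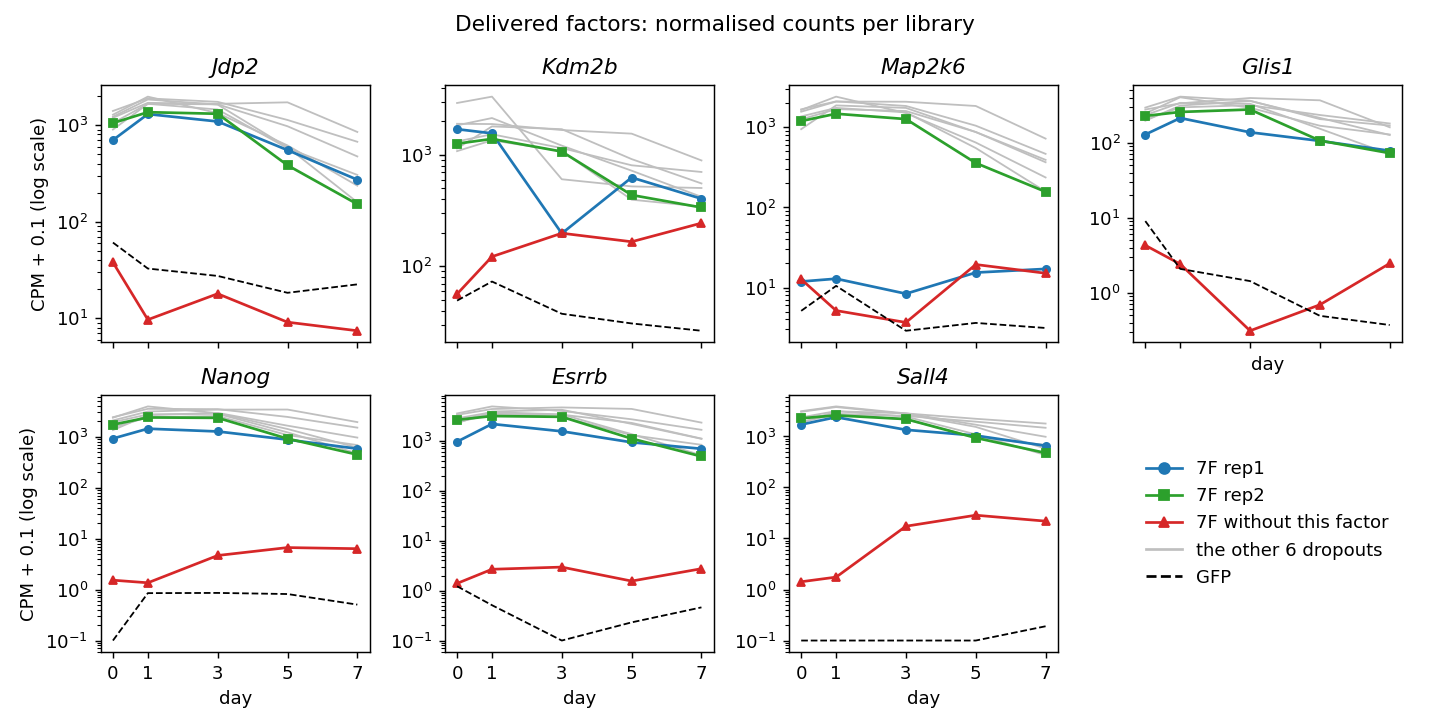
Normalised counts (CPM, log axis) of the 7 delivered factors in the reprogramming libraries by day, 1 panel per gene. Symbols mark 7F replicate 1, 7F replicate 2 and the dropout of that gene. Plain grey lines are the other dropouts and the dashed line is GFP. Map2k6 sits between 8.28 and 17 in the libraries labelled 7F replicate 1 and between 157 and 1480 in those labelled 7F replicate 2.

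The first comparison asks which genes set iPSC lines made with 7F apart from MEFs. All 32 members of the naive pluripotency list rose in the 5 lines (camera adjusted p = 5.28e-45, and adjusted p = 0.00131 with an estimated correlation), and all 32 passed when adjusted over the list alone. Tdgf1, a Nodal co-receptor, was at least 2420-fold higher (250 ± 56.4 CPM, SD, n = 5, against 0 in all 5 MEF libraries, with the floor at 3 counts over the group), and Dppa3, a maternal factor of the early embryo, at least 1170-fold higher. Zfp42, known as Rex1, averaged 273 ± 27.2 against 0.0267 ± 0.0598 CPM (edgeR adjusted p = 6.16e-15). Fibroblast and mesenchymal genes fell, with 37 of 37 lower (camera adjusted p = 3.65e-08, and adjusted p = 0.442 with an estimated correlation). The growth factor receptor Pdgfra was at -7.25 ± 0.49 (log2 fold change, SE), the transcription factor Snai2 at -5.83 ± 0.52 and fibronectin, Fn1, at -3.12 ± 0.28. Fmod, a collagen-binding proteoglycan, was at least 353-fold lower, with no count in the 5 lines. Of 25 epithelial genes 20 rose and 3 fell (camera adjusted p = 7.85e-06, and adjusted p = 0.442 with an estimated correlation), among them the adhesion genes Cdh1 at 9.16 ± 0.46 and Epcam at 7.17 ± 0.43.

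Other gene groups also differed between the 7F iPSC lines and MEF. AP-1 family genes fell (12 of 13 lower and 1 higher, camera adjusted p = 0.00171), as did stress kinase and inflammatory genes (17 of 20 lower and 1 higher, 0.00717) and imprinted genes (16 of 20 lower and 3 higher, 0.000895); each of these lists had an adjusted p = 0.442 with an estimated correlation. Examples were the AP-1 subunit Fosl1 at -6.46 ± 0.58, the prostaglandin synthase Ptgs2 at -8.54 ± 0.69 and the imprinted growth regulator Grb10 at -4.63 ± 0.35. Germ line genes rose (11 of 12 higher, camera adjusted p = 0.00214, and adjusted p = 0.442 with an estimated correlation), including Stk31, at least 141-fold higher than in MEF, where it had no count. Cell cycle genes rose (26 of 30, camera adjusted p = 0.000167, and adjusted p = 0.666 with an estimated correlation), for example the replication gene Mcm2 at 2.21 ± 0.21. Primitive endoderm genes fell (8 of 12 lower and 2 higher, camera adjusted p = 0.0392, and adjusted p = 0.442 with an estimated correlation), and so did blood and macrophage genes (10 of 12 lower and 1 higher, camera adjusted p = 0.0399, and adjusted p = 0.666 with an estimated correlation). The remaining lists were not called by camera. Of those, 8 primed pluripotency genes were higher and 3 lower of 11, 7 glycolysis genes higher and 5 lower of 19 (the glucose transporter Slc2a3 at 6.44 ± 0.33), 10 cholesterol synthesis genes lower and 1 higher of 20, 9 of 13 2-cell-like genes higher, and 7 of 22 oxidative phosphorylation genes higher and 1 lower. Interferon response (11 of 18 lower and 2 higher), p53 and senescence (9 of 22 lower and 6 higher), trophoblast (7 of 12 higher and 5 lower), neural (4 of 8 lower and 3 higher), mesoderm and cardiac (5 of 9 lower and 2 higher), skeletal muscle (3 of 4 lower), endothelial (4 of 8 higher and 3 lower), adipocyte (3 of 4 lower), cartilage and bone (5 of 7 lower and 1 higher) and sex-linked genes (3 of 6 higher and 1 lower) were also not called.

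For the delivered genes themselves, transcripts in the 7F iPSC lines differed from MEF in both directions. Nanog rose by 10.01 ± 0.29 and Esrrb by 11.58 ± 0.32 on the log2 scale, and Sall4 averaged 345 ± 231 against 0.103 ± 0.146 CPM (edgeR adjusted p = 1.92e-11). Map2k6 rose by 3.09 ± 0.24 and Kdm2b by 1.71 ± 0.20, while Jdp2 was lower at -2.87 ± 0.44. Glis1 was not called (-0.98 ± 0.63, edgeR adjusted p = 0.171), although it passed without iPSC line 5, at -1.66. Apart from Glis1, no named gene had overlapping values between the 5 lines and the 5 MEF libraries. For the highest and lowest differences, here and below, this (or the same direction on all 5 days) was a condition of being named. Over all genes, 11073 of 15554 passed an edgeR adjusted p of 0.05, 5809 higher and 5264 lower. With MEF 1 to 3 alone, which share the iPSC lines' length of 74.5 bases in the tables, 10245 genes passed.

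The second comparison puts the lines made from MEFs with Y'F against the same MEF libraries. Tdgf1 was at least 2070-fold higher, Nanog rose by 9.83 ± 0.29 and Cdh1 by 9.05 ± 0.46 (log2, SE, 6 lines against 5 libraries). Mgp, an inhibitor of matrix calcification, was lower at -9.21 ± 0.50 and Pdgfra at -6.54 ± 0.42. Il1rn, the interleukin 1 receptor antagonist, was lower, with no count in the 6 lines, 26.1 to 37.5 CPM in 4 MEF libraries and 136 in MEF 4. Of the 7F factors, Glis1 was lower at -3.52 ± 0.68 and Jdp2 at -2.14 ± 0.39. Line 5 also held fibroblast transcripts, with the collagen gene Col1a1 at 1900 CPM against a mean of 71.1 in the other 5 lines. The edgeR test called 11192 of 15554 genes, 6032 higher and 5160 lower. The count was 10292 with MEF 1 to 3 alone and 10991 without line 5.

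Set against each other, the lines made with 7F and with Y'F from MEFs address, without settling, whether the factor combination leaves a mark in the established line. Nanog averaged 845 ± 97 CPM in 5 lines made with 7F and 743 ± 105 in 6 made with Y'F, a log2 difference of 0.18 ± 0.17. The 13 measured 2-cell-like genes, transcripts of the zygotic genome activation stage, were lower as a group in the 7F lines (camera adjusted p = 0.000823, and adjusted p = 0.984 with an estimated correlation): 0 of them passed over all genes and 6 were lower when adjusted over the list alone. Tmem92, 1 of this list, averaged 1.14 ± 0.533 against 6.36 ± 5.79 CPM (log2 difference -2.51 ± 0.64, edgeR adjusted p = 0.142). Fry called 0 of the 25 lists in this comparison. The germ line list was not called (camera adjusted p = 0.0522); 2 of its 12 genes were higher when adjusted over the list alone, with the meiotic gene Hormad1 at 2.15 ± 0.47 (edgeR adjusted p = 0.138). Glis1 was 2.42 ± 2.09 against 0.404 ± 0.394 CPM (edgeR adjusted p = 0.161). No gene passed in edgeR (0 of 15554, 1702 at an unadjusted p under 0.05), while DESeq2 called 230, Glis1, Hormad1 and Tmem92 among them. With the line number as a block, in a fit that also left out Y'F line 6, MEF and TTF, edgeR called 147, Hormad1 (2.56) among them. The 147 are therefore not due to the block alone. Without 7F iPSC line 5 edgeR called 1 gene, and without Y'F line 5, which held the fibroblast transcripts, it called 0.

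The 2 TTF lines were compared with the 6 lines made from MEFs with the same Y'F combination, a question about the cell of origin. Egr1, an immediate early transcription factor, was higher (111 and 14.5 CPM in the 2 lines against 0.531 ± 0.332, SD, n = 6; log2 6.81 ± 0.67, edgeR adjusted p = 5.82e-06), as was Klhl3, an adaptor of a ubiquitin ligase, at 3.88 ± 0.59. Among pluripotency genes Zfp42 was lower at -1.71 ± 0.22 (88.7 ± 6.63 against 294 ± 55.2 CPM), whereas Nanog differed by -0.03 ± 0.24. Dppa3 was lower at -2.60 ± 0.49, a call that ended when either TTF line was left out (-2.67 to -2.54) or only these groups were fitted (-2.60). Kdm2b was higher at 1.29 ± 0.23, a call that ended without TTF line 2 (1.14) and with only these groups fitted (1.28). Processed pseudogenes made up 37 of the 107 lower genes. Rpl34-ps1 (chromosome 6, 71124610 to 71124963, GRCm38) was lower at -7.42 ± 0.44 and Rps3a2 (chromosome 14, 88123017 to 88123808) at -8.66 ± 0.52, with no count in TTF line 2. Pcna-ps2 (chromosome 19, 9283380 to 9284160) was at least 105-fold lower, with no count in either TTF line. These counts are uncertain, because reads of a pseudogene and its parent can be divided between them. Of the 25-base words of Rpl34-ps1, 84.8% also occur in Rpl34, 87.2% of those of Rps3a2 in Rps3a1 and 80.2% of those of Pcna-ps2 in Pcna. Of the named genes only Nanog had overlapping values between the groups. In all, 177 of 15554 genes passed in edgeR, 70 higher and 107 lower. The count fell to 53 without either TTF line, was 79 when only these groups were fitted, 390 in DESeq2 and 214 without Y'F line 5.

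The time course of the libraries labelled complete 7F shows the order of events between infection and day 7 (2 libraries per day, log2 fold change against day 0 with SE, edgeR). On day 1 the pluripotency factor Sox2 rose by 3.36 ± 0.23 and the threonine dehydrogenase Tdh from 0.235 ± 0.332 to 78.6 ± 11.8 CPM (edgeR adjusted p = 0.00118), while Cnn1 (-4.68 ± 0.25), Acta2 (-3.93 ± 0.29) and Col1a1 (-2.89 ± 0.19) fell. By day 3 Acta2 was at -6.35 ± 0.33 and Lox, a collagen cross-linking enzyme, at -6.51 ± 0.48. The growth factor Fgf17 was at least 123-fold higher and the hormone gene Trh at least 509-fold higher, with 145 ± 147 CPM on day 3 and no count on day 0. On day 5 the pluripotency gene Dppa5a was at least 480-fold, Tdgf1 at least 96-fold and the epithelial splicing regulator Esrp1 at least 66-fold above day 0.

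By day 7, 27 of 32 naive pluripotency genes were higher than on day 0, and 28 when adjusted over the list alone (camera adjusted p = 1.54e-20, and adjusted p = 0.152 with an estimated correlation). Dppa5a reached 268 ± 73.2 CPM (at least 941-fold), Fgf4 was at least 73.3-fold higher, the DNA demethylase Tet1 rose by 3.86 ± 0.26 and Sox2 by 3.51 ± 0.23. Fibroblast genes fell (18 of 37 lower and 2 higher, camera adjusted p = 1.8e-16), AP-1 family genes fell (9 of 13 lower, 9.75e-09) and stress kinase and inflammatory genes fell (12 of 18 lower and 1 higher, 3e-09); for each the adjusted p = 0.152 with an estimated correlation. Acta2 was at -7.70 ± 0.35, S100a4 at -6.45 ± 0.32, Col1a1 at -3.43 ± 0.20, the AP-1 subunits Junb at -3.90 ± 0.21 and Fosl2 at -3.18 ± 0.16, the cytokine Il11 at -6.14 ± 0.41 and Ptgs2 at -5.12 ± 0.42. Epithelial genes rose (16 of 25 higher and 3 lower, camera adjusted p = 1.04e-05, and adjusted p = 0.356 with an estimated correlation), with Epcam at 6.82 ± 0.95. Glycolysis genes rose (10 of 19, 0.0011, and adjusted p = 0.356 with an estimated correlation), with Slc2a3 at 5.28 ± 0.53 and Aldoc at 4.15 ± 0.67. Endothelial genes rose (8 of 12 higher and 2 lower, 0.0116, and adjusted p = 0.343 with an estimated correlation), with the junction gene Cdh5 at 5.12 ± 0.43. Genes of p53 and senescence fell (10 of 22 lower and 3 higher, 0.00162, and adjusted p = 0.291 with an estimated correlation), with the p53 regulator Mdm2 at -2.07 ± 0.22.

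Smaller lists on day 7 were primed pluripotency (7 of 12 higher and 2 lower, camera adjusted p = 0.00653, and adjusted p = 0.411 with an estimated correlation), germ line (3 of 5 higher, 0.0498, and adjusted p = 0.307 with an estimated correlation) and skeletal muscle (3 of 5 lower, 0.0179, and adjusted p = 0.313 with an estimated correlation), all called. Keratinocyte genes, 1 higher and 2 lower of 4, were not called (camera adjusted p = 0.495). The primitive endoderm list was not called (0.0929) unless the replicate number was fitted as a block (camera adjusted p = 0.0377, and adjusted p = 0.269 with an estimated correlation). Of 15098 genes, edgeR called 1808 on day 1 (842 higher, 966 lower), 2819 on day 3 (1401 and 1418), 4021 on day 5 (1997 and 2024) and 4325 on day 7 (2157 and 2168). With the replicate block the counts were 3286 on day 1, 4471 on day 3, 5892 on day 5 and 6342 on day 7. Leaving out 1 library in turn gave 494 to 720 genes on day 1, 1282 to 2447 on day 3, 2131 to 2525 on day 5 and 2338 to 2991 on day 7.

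A reprogramming position was computed per library, with the MEF mean at 0 and the 7F iPSC mean at 1, from the 500 genes that rose most and the 500 that fell most between them. The libraries labelled complete 7F stood at 0.085 ± 0.004 (SD, n = 2) on day 0, 0.242 ± 0.002 on day 1, 0.306 ± 0.047 on day 3, 0.462 ± 0.039 on day 5 and 0.454 ± 0.026 on day 7. GFP, with 1 library per day, stood at 0.025 on day 0, 0.098 on day 1 and 0.075 on day 7. On day 7 the single dropout libraries stood at 0.276 without Esrrb, 0.276 without Sall4, 0.306 without Glis1, 0.327 without Nanog, 0.342 without Jdp2, 0.384 without Mkk6 and 0.501 without Kdm2b. These dropout values have no replicate and no test. The equal values without Esrrb and without Sall4 came from unlike parts. Scaled in the same way, the 500 rising genes stood at 0.146 without Esrrb and 0.344 without Sall4 on day 7. The 500 falling genes stood at 0.394 and 0.214, where 1 is the 7F iPSC level. In 7F replicates 1 and 2 the rising part was 0.472 and 0.539 and the falling part 0.402 and 0.413.

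**Figure D2:**
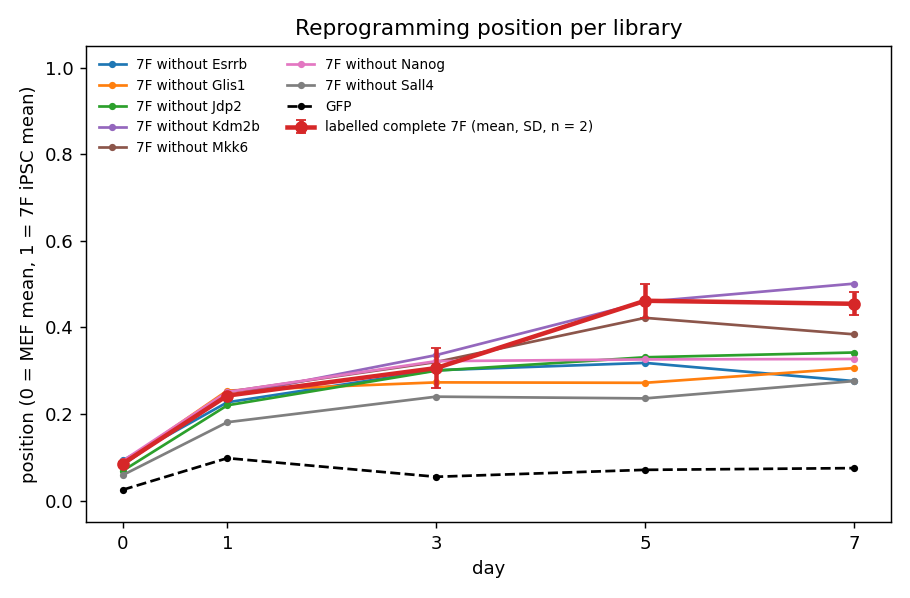
Reprogramming position (no unit, 0 at the MEF mean and 1 at the 7F iPSC mean) by day for each reprogramming arm. The line for the libraries labelled complete 7F gives the mean with SD as error bars (2 libraries per day, 0.454 on day 7), the other lines are single libraries, and GFP ends at 0.075.

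The libraries labelled complete 7F were compared with GFP as a shift common to the 5 days, 10 libraries against 5, with days standing in for replicates of GFP. All 7 delivered genes were higher: Esrrb by 12.36 ± 0.77, Nanog by 10.98 ± 0.46, Glis1 by 6.89 ± 0.59, Jdp2 by 4.51 ± 0.39 and Kdm2b by 4.32 ± 0.38, with Sall4 at 1560 ± 772 against 0.0181 ± 0.0404 CPM. Map2k6 was higher by 1.62 with replicate 1 alone, where it stayed near GFP, and by 7.29 with replicate 2 alone. Naive pluripotency genes rose (27 of 32 higher and 1 lower, camera adjusted p = 2.06e-11), Sox2 by 7.82 ± 0.50 and L1td1, an RNA-binding gene of stem cells, by 8.08 ± 0.79. Epithelial genes rose (19 of 24, 1.5e-07), Cdh1 by 8.77 ± 0.57. Igdcc3, a cell surface receptor of the DCC family, was at least 2090-fold higher. Interferon response genes fell, with 23 of 24 lower and all 24 when adjusted over the list alone (camera adjusted p = 2.69e-07), among them the signalling factor Stat2 at -2.15 ± 0.28 and Xaf1 at -3.59 ± 0.48. Fibroblast genes fell (29 of 37 lower and 2 higher, 2.88e-09), with the proteoglycans Dcn at -5.80 ± 0.82 and Lum at -5.59 ± 0.70 and the filament gene Vim at -2.43 ± 0.22. Genes of p53 and senescence fell (16 of 22 lower and 2 higher, 0.00168), with the cell cycle inhibitor Cdkn2b at -2.73 ± 0.30. For these 5 lists the adjusted p = 0.337 with an estimated correlation.

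Cholesterol synthesis genes were also lower than in GFP (12 of 20, camera adjusted p = 0.00149, and adjusted p = 0.429 with an estimated correlation), with the sterol enzymes Msmo1 at -1.59 ± 0.24 and Cyp51 at -1.51 ± 0.24, and cell cycle genes were higher (13 of 30 higher and 1 lower, 0.000628, and adjusted p = 0.561 with an estimated correlation). Lists also called were primed pluripotency (10 of 12 higher, 0.00149), endothelial (8 of 12 higher, 0.00132), trophoblast (8 of 14 higher and 1 lower, 0.00287), mesoderm and cardiac (4 of 9 higher, 0.045), keratinocyte (2 of 4 higher, 0.045) and blood and macrophage genes (6 of 8 lower and 1 higher, 0.0317), each with an adjusted p = 0.337 with an estimated correlation. Il1rl1, an interleukin 33 receptor, was lower at -6.43 ± 0.41. The test called 8058 of 15212 genes in edgeR, 4045 higher and 4013 lower. It called 4842 with replicate 1 alone and 4726 with replicate 2 alone as complete 7F. The mean read or fragment length in the tables was 35 bases on GFP days 1 to 7 and 203.1 on GFP day 0, against 74.5 in 7F replicate 2 and 167.1 to 171.1 in replicate 1. Esrrb was 0 to 1.12 CPM in GFP and 484 to 3110 in 7F over libraries of all these lengths. The reprogramming position was 0.025 to 0.098 in GFP, and 0.436 and 0.473 in the day 7 libraries of 7F replicates 1 and 2. Only day 0 has both arms at over 150 bases, with 1 library of each, too few for a test. For single genes other than those delivered, and for the gene lists, the kind of library and the arm are therefore not separated.

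A separate term tested whether the change per day differed between 7F and GFP. Cell cycle genes differed most evenly: 28 of 30 changed more upward per day in 7F (camera adjusted p = 7.41e-30, and adjusted p = 0.0857 with an estimated correlation), among them the mitotic genes Aurkb by 0.82 ± 0.09, Cdc20 by 0.80 ± 0.09 and Plk1 by 0.76 ± 0.09 on the log2 scale per day. Cdc20 averaged 130 ± 29.9 CPM in 7F and 73.6 ± 82.9 in GFP. Within 7F the cell cycle list was not called on day 7 against day 0 (camera adjusted p = 0.152). There 6 of 30 genes were higher and 1 lower. The term therefore does not show a rise of this list in 7F itself, and it depends also on the change in GFP, with 1 library per day. Genes of p53 and senescence changed more downward (9 of 22, camera adjusted p = 2.05e-05, and adjusted p = 0.15 with an estimated correlation), with Mdm2 at -0.52 ± 0.06 and the cyclin G gene Ccng1 at -0.58 ± 0.08, as did stress kinase and inflammatory genes (7 of 19, 0.000131, and adjusted p = 0.15 with an estimated correlation), with the chemokine Ccl7 at -0.85 ± 0.12. Interferon response genes went the same way (5 of 24, 1.9e-05, and adjusted p = 0.489 with an estimated correlation), with Ifit2 at -0.78 ± 0.09, and Serpina3n, a protease inhibitor of the acute phase, was at -1.12 ± 0.18. The interferon list was likewise not called within 7F on day 7 (5 of 22 lower, camera adjusted p = 0.0813). Glycolysis genes changed more upward (9 of 19, 3.89e-05, and adjusted p = 0.284 with an estimated correlation), as did naive (7 of 32, 0.00348) and primed pluripotency (5 of 12, 0.0102) and epithelial genes (5 of 25 and 1 downward, 0.00926). Fibroblast genes changed more downward (10 of 37 and 1 upward, 0.000129); for the last 4 lists the adjusted p was 0.489 to 0.564 with an estimated correlation. The edgeR test called 2766 of 15864 genes, 1473 upward and 1293 downward. It called 560 with replicate 1 alone and 907 with replicate 2 alone, and leaving out days gave 3769 (day 0), 1516 (day 1), 1057 (day 5) and 1135 (day 7). GFP day 0 (203.1 bases, 1.9 M counts) differs in kind of library from GFP days 1 to 7 (35 bases, 19.04 to 29.23 M counts). The mitochondrial share of counts in GFP was 1.44, 1.17, 2.77, 4.63 and 6.05% on days 0, 1, 3, 5 and 7. It was 2.63 to 5.57% in 7F replicate 1, highest on day 3, and 1.3 to 2.71% in replicate 2. Whether this bears on the change per day was not tested. On simulated data edgeR recovered 0 of 100 changes that grew evenly on the log2 scale to 4-fold on day 7. Per day these were smaller than the changes named above, so the simulation does not answer for changes of that size.

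Each dropout was compared with the libraries labelled complete 7F as a shift common to the 5 days (5 libraries against 10, log2 difference with SE, edgeR over 15957 genes), to learn what the missing factor adds to the others. Because replicate 1 has Map2k6 at the level of its dropout and differs in kind of library, each count is also given with replicate 2 alone, which shares the dropouts' length of 74.4 or 74.5 bases in the tables. The gene lists were tested only against both replicates together and not with replicate 2 alone. A list difference is therefore not separated from what sets replicate 1 apart. All dropouts share this reference, and some lists recur. Oxidative phosphorylation was called higher without Glis1, Sall4, Nanog or Mkk6 and lower without Esrrb. Cholesterol synthesis was called higher without Esrrb, Jdp2, Nanog or Mkk6. Differences between 1 dropout and another were not tested.

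Without Esrrb, Esrrb itself was at -9.40 ± 0.37 and naive pluripotency genes fell: 22 of 32 were lower, and 26 lower with 1 higher when adjusted over the list alone (camera adjusted p = 1.04e-11, and adjusted p = 0.359 with an estimated correlation). Dppa5a was at -8.06 ± 0.90, Zfp42 at -5.66 ± 0.93 and Tfcp2l1, a transcription factor of the naive state, at -4.78 ± 0.61. Metabolic genes fell, with glycolysis at 11 of 19 lower and 1 higher (camera adjusted p = 3.73e-07, and adjusted p = 0.359 with an estimated correlation) and oxidative phosphorylation at 10 of 23 lower (1.18e-05, and adjusted p = 0.464 with an estimated correlation); Hk1 was at -1.70 ± 0.21, Pfkp at -1.68 ± 0.22 and Gpi1 at -0.95 ± 0.17. Epithelial genes fell (11 of 24 lower and 3 higher, 0.0056, and adjusted p = 0.618 with an estimated correlation), with the protease inhibitor Spint2 at -2.28 ± 0.30, while fibroblast genes rose (7 of 37 higher and 2 lower, 0.00124, and adjusted p = 0.557 with an estimated correlation). Among the highest differences were Col8a2 at 4.27 ± 0.50, A2ml1 at 4.07 ± 0.37 and Matn1 at 3.92 ± 0.51. Also called were the primitive endoderm list, lower (3 of 18, 0.00975, and adjusted p = 0.464 with an estimated correlation), and the cholesterol synthesis list, higher (1 of 20, 0.00993, and adjusted p = 0.68 with an estimated correlation). The trophoblast list was not called and its members went both ways, with Eomes at -2.87 ± 0.31 and Gata2 at 2.20 ± 0.32. Each named gene differed in the direction given on all 5 days, except Dppa5a (4 of 5). In all, 2753 genes passed, 1173 higher and 1580 lower, with 1907 against replicate 2 alone and 4833 against the mean of the other 6 dropouts. Without day 1 the count was 1795 and without day 3 it was 1432.

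Without Glis1, Glis1 was at -6.27 ± 0.33, and 23 of 37 fibroblast and mesenchymal genes were higher with 1 lower (26 and 1 adjusted over the list alone; camera adjusted p = 3.44e-10, and adjusted p = 0.46 with an estimated correlation). Tgfbi, a matrix protein induced by TGF-beta, was at 1.87 ± 0.25 and Col1a2 at 1.39 ± 0.20. Naive pluripotency genes fell (18 of 32 lower, 1.74e-05, and adjusted p = 0.572 with an estimated correlation), with Sox2 at -3.82 ± 0.37, Lin28a, an RNA-binding repressor of let-7, at -3.51 ± 0.66 and Dppa5a at -3.50 ± 0.59. Genes of p53 and senescence rose (10 of 22 higher and 1 lower, 0.000138, and adjusted p = 0.572 with an estimated correlation), with the cell cycle inhibitors Cdkn2a at 1.41 ± 0.19 and Cdkn1a at 0.96 ± 0.17 and the stress cytokine Gdf15 at 2.30 ± 0.34. Interferon response genes rose (9 of 24 higher, 0.000138, and adjusted p = 0.693 with an estimated correlation) and cell cycle genes fell (7 of 30 lower, 0.00024, and adjusted p = 0.791 with an estimated correlation), with the topoisomerase Top2a at -0.87 ± 0.18. The AP-1 family (3 of 15 higher, 0.0402, and adjusted p = 0.693 with an estimated correlation) and oxidative phosphorylation (5 of 23 higher, 0.0151, and adjusted p = 0.791 with an estimated correlation) were also called. Thrsp, a regulator of fat synthesis, was at 3.63 ± 0.30, the insulin-responsive glucose transporter Slc2a4 at 3.13 ± 0.37 and Il11 at -4.62 ± 0.63. Dcpp1 averaged 0.0394 ± 0.0881 against 18.4 ± 19.6 CPM (edgeR adjusted p = 1.86e-06). The delivered genes Esrrb (1.13 ± 0.21) and Nanog (1.16 ± 0.26) were higher than in the libraries labelled complete 7F. That reference was also lower than the dropouts in general, this arm included. Esrrb averaged 2810 CPM over the 30 dropout libraries given Esrrb, 1250 in 7F replicate 1 and 2060 in replicate 2. Nanog averaged 2190 over the 30 given Nanog, against 1020 and 1570. Each named gene differed in the direction given on all 5 days, except Lin28a and Cdkn1a (4 of 5). In all, 3522 genes passed, 1894 higher and 1628 lower, 2084 with replicate 2 alone and 1807 with only these arms fitted; without day 3 the count was 2182 and without day 5 it was 1524. Dppa5a was not called against the mean of the other 6 dropouts (-0.22).

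Without Jdp2, Jdp2 was at -5.46 ± 0.35 and genes of AP-1 and stress signalling rose: 6 of 15 AP-1 family genes (camera adjusted p = 0.000925) and 6 of 20 stress kinase and inflammatory genes, with 1 lower (0.000446), each with an adjusted p = 0.572 with an estimated correlation. Il11 was at 3.13 ± 0.36, the stress response factor Atf3 at 2.31 ± 0.31, Il1rl1 at 1.52 ± 0.27 and Maff at 1.02 ± 0.21. Vasopressin, Avp, was at 6.58 ± 0.64, peptide YY, Pyy, at 5.23 ± 0.37 and the calcium-binding gene Efhd1 at 4.59 ± 0.34. Endothelial genes rose (4 of 12 higher, and 8 adjusted over the list alone; 0.000464, and adjusted p = 0.28 with an estimated correlation), with Cdh5 at 2.59 ± 0.29 and the VEGF receptor Flt1 at 1.46 ± 0.25. Cholesterol synthesis genes rose (7 of 20, 0.000464, and adjusted p = 0.797 with an estimated correlation), with Hsd17b7 at 0.64 ± 0.14. Other called lists were cell cycle (1 of 30 lower, 0.000464), glycolysis (3 of 19 lower, 0.036) and primitive endoderm (3 of 18 higher, 0.0358), each with an adjusted p = 0.797 with an estimated correlation. Naive pluripotency genes fell (18 of 32 lower and 1 higher, 3.14e-06, and adjusted p = 0.572 with an estimated correlation), with Dppa5a at -4.39 ± 0.65 and Dnmt3l, a cofactor of DNA methylation, at -4.36 ± 0.81; neither was called against the mean of the other 6 dropouts (-1.26 and -2.03), nor Dppa5a in DESeq2 (-2.67). Named genes kept their direction on all 5 days, apart from Dppa5a (4 of 5). The test called 1924 genes, 1227 higher and 697 lower, with 976 against replicate 2 alone and 3321 against replicate 1 alone. Without day 1 the count was 1232, without day 3 it was 748 and without day 5 it was 725.

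Without Sall4, Sall4 was at -6.29 ± 0.51 and proliferation genes fell: 29 of 30 cell cycle genes were lower (camera adjusted p = 2.83e-26, and adjusted p = 0.132 with an estimated correlation), with the mitotic kinases Aurka at -1.27 ± 0.15 and Cdk1 at -1.10 ± 0.13 and the replication gene Mcm6 at -1.05 ± 0.13. Of 32 naive pluripotency genes 29 were lower (2.31e-05, and adjusted p = 0.622 with an estimated correlation), with Fgf17 at -2.81 ± 0.52 and Tet1 at -2.07 ± 0.39. Gldc, the glycine decarboxylase, was at -3.75 ± 0.49 and Slc2a3 at -2.46 ± 0.46, and glycolysis genes fell (12 of 19 lower and 2 higher, 0.00528, and adjusted p = 0.622 with an estimated correlation). Fibroblast genes rose (20 of 37 higher and 1 lower, 0.000134), as did stress kinase and inflammatory genes (15 of 20 higher, 5.32e-05), each with an adjusted p = 0.622 with an estimated correlation, and AP-1 family genes (11 of 15 higher and 1 lower, 0.000494, and adjusted p = 0.549 with an estimated correlation). Interferon response (11 of 24 higher, 0.0115), p53 and senescence (11 of 22 higher, 0.00528) and oxidative phosphorylation genes (11 of 23 higher and 1 lower, 0.0326) also rose, with adjusted p of 0.622 to 0.748 with an estimated correlation. Col3a1 was at 1.48 ± 0.20, the phosphatase Dusp1 at 1.45 ± 0.20, Il11 at 2.37 ± 0.38 and Il1rl1 at 1.99 ± 0.27. The photoreceptor transporter Abca4 was at 3.82 ± 0.40 and the neuronal gene Rtn1 at 3.50 ± 0.36. Of the delivered genes, Esrrb (1.41 ± 0.21) and Nanog (1.30 ± 0.26) were higher than in the libraries labelled complete 7F. Here too the reference was lower than the dropouts in general, this arm included. Esrrb averaged 2810 CPM over 30 dropout libraries, against 1250 in 7F replicate 1 and 2060 in replicate 2. For Nanog the means were 2190, 1020 and 1570. Named genes kept their direction on all 5 days. In all, 6981 genes passed, 3571 higher and 3410 lower, and 5796 with replicate 2 alone. Without day 5 the count was 4483.

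Without Nanog, Nanog was at -8.11 ± 0.43 and 10 of 32 naive pluripotency genes were lower, or 25 when adjusted over the list alone (camera adjusted p = 5.26e-11, and adjusted p = 0.365 with an estimated correlation). Dppa5a was at -3.65 ± 0.62, Utf1 at -3.50 ± 0.70, Tdgf1 at -3.37 ± 0.64 and Tfcp2l1 at -2.40 ± 0.48, while Pyy was at 1.95 ± 0.40 and the cytochrome gene Cyp2s1 averaged 95.8 ± 87.8 against 34.2 ± 29.8 CPM. Cell cycle genes fell as a list (camera adjusted p = 8.25e-07, and adjusted p = 0.567 with an estimated correlation), with 0 passing over all genes in edgeR and 8 lower adjusted over the list alone. AP-1 family genes rose as a list (0.00016, and adjusted p = 0.365 with an estimated correlation), with 0 passing over all genes and 5 higher adjusted over the list alone, and oxidative phosphorylation genes rose likewise (2.47e-05, and adjusted p = 0.474 with an estimated correlation), with 9 higher and 1 lower adjusted over the list alone. Glycolysis, lower (1 of 19, 0.000789), endothelial, higher (0 of 12, 0.0135), and cholesterol synthesis, higher (0 of 20, 0.0135), were called too, with adjusted p of 0.431 to 0.83 with an estimated correlation. Fry called 3 of the 25 lists in this comparison, where camera called 7. Named genes kept their direction on all 5 days, apart from Tdgf1 (4 of 5) and Dppa5a (3 of 5). The count was 100 genes, 44 higher and 56 lower, with 3205 at an unadjusted p under 0.05, 382 in DESeq2 and 305 with no low-count filter. It was 28 against replicate 2 alone, 2629 against replicate 1 alone, 222 against the other 6 dropouts, 16 with only these arms fitted and 413 on days 3 to 7. It rested on single days: 178 without day 0, 63 without day 1, 2 without day 3, 2 without day 5 and 4 without day 7. Tdgf1 (-4.28 to -2.85), Tfcp2l1 (-2.34 to -2.01), Utf1 (-4.26 to -3.26), Pyy (1.64 to 1.87) and Cyp2s1 (1.23 to 1.51) were each not called without day 3, day 5 or day 7, and Dppa5a without day 5 or day 7 (-3.31 and -3.23). Against the mean of the other 6 dropouts Dppa5a (-0.39), Utf1 (-0.97), Tdgf1 (-1.56) and Tfcp2l1 (-0.62) were not called. Nor were Dppa5a in DESeq2 (-1.83) and Cyp2s1 with replicate 2 alone (1.56). With only the 2 arms fitted Dppa5a (-3.63), Tdgf1 (-3.50), Utf1 (-3.77) and Pyy (2.16) were not called.

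Without Mkk6, Map2k6 averaged 11.1 ± 6.67 CPM against 453 ± 610 in the libraries labelled complete 7F, of which replicate 1 held 8.28 to 17; the difference of -4.69 ± 0.99 was not called (edgeR adjusted p = 0.101), and it passed against replicate 2 alone (-5.72), against the other 6 dropouts (-6.32), in DESeq2 (-4.55) and with no low-count filter (-4.70). Oxidative phosphorylation genes were higher as a list (camera adjusted p = 3.92e-06, and adjusted p = 0.626 with an estimated correlation), with 0 passing over all genes and 10 higher and 1 lower adjusted over the list alone. Naive pluripotency genes were lower as a list (0.00917, and adjusted p = 0.745 with an estimated correlation) with 0 of 32 passing, and Klf5 differed by -0.63 ± 0.22 (edgeR adjusted p = 0.162; called with replicate 1 alone, -0.70). The other 5 called lists also had 0 genes passing: stress kinase and inflammatory (0.0266), trophoblast (0.0393), blood and macrophage (0.0266) and sex-linked genes (0.0393), lower, and cholesterol synthesis (0.0266), higher, with adjusted p of 0.626 to 0.745 with an estimated correlation. Fry called 0 of the 25 lists in this comparison. Map2k6 and Klf5 kept their direction on all 5 days. Over all genes edgeR called 0, with 2467 at an unadjusted p under 0.05 235 in DESeq2 and 53 with no low-count filter. With replicate 2 alone it called 1, with replicate 1 alone 2399, with only these arms fitted 2 and against the other 6 dropouts 879.

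Without Kdm2b, Kdm2b averaged 157 ± 71.9 CPM against 898 ± 561, a difference of -2.04 ± 0.40 that was not called over the 5 days (edgeR adjusted p = 0.0691). It passed without day 7 (-2.64), against the other 6 dropouts (-2.57), with replicate 1 alone (-2.02), in DESeq2 (-2.03) and with no low-count filter (-2.03). The single gene that passed was Gm12397 (chromosome 4, 40912741 to 40913355, GRCm38), a processed pseudogene at -2.89 ± 0.52 (edgeR adjusted p = 0.037), which is named here after its values were seen. All 591 of its 25-base words also occur in Kdm2b, so its reads cannot be separated from those of Kdm2b. Genes of p53 and senescence were higher as a list (camera adjusted p = 0.0145), primitive endoderm genes lower (0.0145) and glycolysis genes lower (0.0456), with 0 members passing over all genes and an adjusted p = 0.926 with an estimated correlation for each. Fry called 0 of the 25 lists in this comparison. Gapdh differed by -1.11 ± 0.27 (edgeR adjusted p = 0.359) and the endocytic adaptor Dab2 by -0.47 ± 0.13 (edgeR adjusted p = 0.499). Gapdh passed in DESeq2 (-1.11), with no low-count filter (-1.10) and with replicate 1 alone (-1.70), and Dab2 with replicate 1 alone (-0.71). Kdm2b, Gapdh and Dab2 kept their direction on all 5 days. At an unadjusted p under 0.05 there were 1127 genes, DESeq2 called 10 and edgeR with no low-count filter 12. Against the other 6 dropouts edgeR called 155, and with only these arms fitted or on days 3 to 7 it called 0. Leaving out days gave 0 genes (days 0, 1, 3 and 5) and 2 (day 7), and replicate 1 alone as the reference gave 1426 against 1 with replicate 2 alone.

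**Figure D3:**
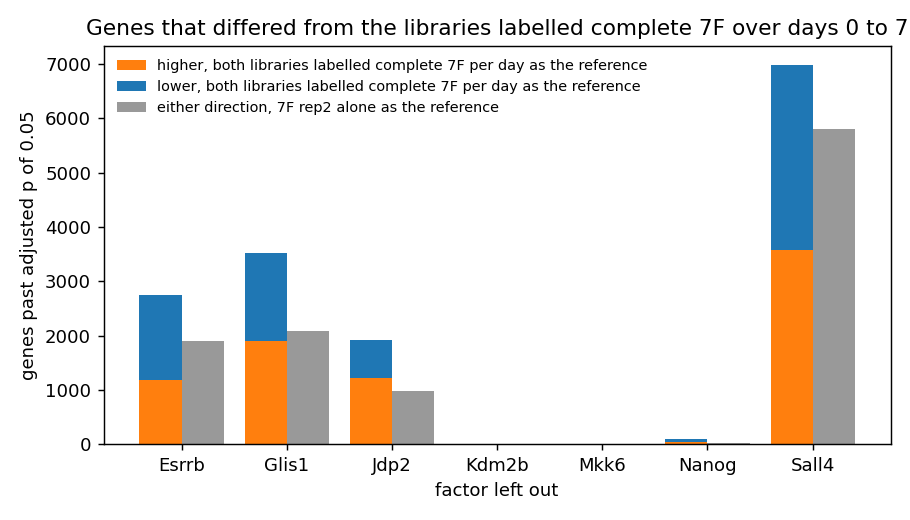
Number of genes past an edgeR adjusted p of 0.05 in each dropout against the libraries labelled complete 7F over days 0 to 7, higher and lower, beside the number with 7F replicate 2 alone as the reference. The dropout without Sall4 has 6981 genes (5796 with replicate 2 alone) and the dropout without Mkk6 has 0 (1 with replicate 2 alone).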

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

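Of 69 groups of values tested for a sample far from the others, 7 gave a flag, and chance flags about 1 in 20 groups. Sall4 was 755 CPM in 7F iPSC line 2, with the next line at 272. Jdp2 was 44.3 CPM in the Y'F line 3 made from MEFs, with the next at 15.1, and Rps3a2 was 556 CPM in the same line, with the next at 459. Il1rn was 136 CPM in MEF 4 (next 37.5), Zfp42 was 0.134 CPM there (0 in the other 4), and this library's total of 22.8 M counts was also far from the next, 5.54. Fosl1 was 48.1 CPM in MEF 1, with the next at 21.4. A difference between groups was flagged by a test for 2766 genes, whose change per day differed between 7F and GFP.

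The 8 tests of the next 3 patterns were chosen after the result was seen. The first is Map2k6 at the level of the dropout in all libraries labelled 7F replicate 1. A swap with the libraries labelled without Mkk6 is excluded, because the highest of those held 19.3 CPM, whereas replicate 2 held at least 157. A loss of delivered-gene counts in general through the kind of library of replicate 1 is excluded, since the lowest ratio of replicate 1 to replicate 2 among the other 6 factors was 0.607 (Esrrb) and that of Map2k6 was 0.0146. Libraries made without the Mkk6 vector stay open: that 5 of 5 had Map2k6 no higher than the highest dropout library restates the pattern and does not test it.

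The second pattern is the lower processed pseudogenes in the TTF lines, 37 of 107 lower genes, with 4 higher and 467 not called (two-sided Fisher's exact test, odds ratio 16.8, p = 2.6e-28). A fall of processed pseudogenes in general is excluded, as the median log2 fold change of all 508 tested was 0.08. Reads divided differently between a pseudogene and its parent gene remain open. Parents were assigned mostly from the form of the symbol, which placed only 9 of the 37 in 8 families. The rest had no parent assigned and were not examined. Of the 8 families 3, with 4 of the 37, held enough pseudogene counts to answer. In all 3 the sum of both differed by less than 25% (Rps3a1, 1540 against 1530 CPM). A donor genome without these copies is open too, as 25 of the 37 were under 5% of the other lines' mean in both TTF lines but no label gives a strain. These explanations cannot be told apart for the 37 genes, because 33 had no parent assigned or a family unable to answer, and strains are unknown.

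The third pattern is the fibroblast transcripts of the Y'F line 5 made from MEFs, where Col1a1 was 1900 CPM. Cells or reads of the MEF profiled here mixed in would give a constant ratio over genes. The spread of the log2 ratio of line 5 to MEF was 1.28, against 0.62 between MEF sets, which excludes a mixture with these MEFs alone. Fibroblast-like or differentiated cells within the line stay open: that 33 of 38 fibroblast list genes were highest in line 5 restates the pattern. Over 172 genes with over 50 CPM in MEF 1 to 3 and over 100 times the mean of the other 5 lines there, the median level in line 5 was 5% of MEF.

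Other splits of the samples, planned before, were run 50 times per comparison, the real one included. As many genes as in the real grouping were called in 1 split for 7F iPSC against MEF (11073; highest other 2), 1 for Y'F against MEF (11192; highest other 8575, which is the real grouping with the names reversed and 1 line misplaced), 50 for 7F against Y'F lines (0; highest other 7; with 0 called every split calls as many, so this count says nothing), 1 for 7F against GFP (8058; highest other 2065), and 2 for the difference in change per day (2766; highest other 3251, from exchanging 1 GFP library with 1 7F library, so single libraries weigh heavily in this count). For the dropouts, fitted with complete 7F alone, the numbers were 2 for Esrrb (1847; highest other 1921), 1 for Glis1 (1807; 1739), 2 for Jdp2 (1284; 2535), 50 for Kdm2b (0; 3302; again empty), 4 for Mkk6 (2; 3668), 3 for Nanog (16; 3295) and 1 for Sall4 (5033; 1338). In every dropout the highest other split set all 7F replicate 1 libraries apart, which points to a structure of the samples. The low Map2k6 is not its whole cause, as replicate 1 alone (8.28 to 17 CPM) and the Mkk6 dropout (3.57 to 19.3) differed in 2399 genes; other causes were not tested. With replicate 2 alone, which shares the dropouts' length in the tables, the counts were 1907 (Esrrb), 2084 (Glis1), 976 (Jdp2), 1 (Kdm2b), 1 (Mkk6), 28 (Nanog) and 5796 (Sall4). An effect of chance is not excluded for the dropouts of Mkk6 and Nanog, and with 0 genes called the splits cannot answer for Kdm2b. For Esrrb and Jdp2 setting replicate 1 apart called more genes than the real grouping, and for Glis1 nearly as many (1739 against 1807). For these 3 the number of genes called is therefore not told apart from such a structure. Days of a series were treated as replicates although replicate differences correlated across days (r from 0.434 to 0.597), so a difference between series of libraries is not excluded for any dropout, each being 1 series.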

How the results depend on the processing

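No reported value changed direction while called. Of 2008 gene values under alternatives 1953 kept their side of the threshold, 36 lost the call and 19 gained it. Most of these genes were picked from the same data for large differences or small adjusted p, so this share does not describe genes in general. The replicate block changed no call of 28 time course gene results and changed 1 list call. It gave 3286 genes on day 1, 4471 on day 3, 5892 on day 5 and 6342 on day 7. The alternatives without Y'F line 5 were chosen after seeing the data, and moved no count by more than 1.5 times. Lines 7F against Y'F: 1 gene with no filter, 230 in DESeq2, 0 to 1 leaving out a 7F line, 0 without Y'F line 5. The count was 147 with the line number as a block, a fit that also left out Y'F line 6, MEF and TTF. The remaining Y'F lines were not left out in turn. TTF: 390 in DESeq2, 79 with these groups alone, 53 without either TTF line. Leaving out a library gave 494 to 720 (day 1), 1282 to 2447 (day 3), 2131 to 2525 (day 5) and 2338 to 2991 (day 7), with fewer samples. 7F against GFP: 4842 and 4726 with replicates 1 and 2 alone. Change per day: 560 and 907 with replicates 1 and 2 alone, 1057 to 3769 leaving out a day. With 1 replicate there are fewer samples.

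Leaving out a day gave 1432 to 2794 genes (Esrrb), 1524 to 3999 (Glis1), 725 to 1996 (Jdp2), 0 to 2 (Kdm2b), 2 to 178 (Nanog) and 4483 to 7065 (Sall4). Replicate 1 alone gave 3321 (Jdp2), 1426 (Kdm2b), 2399 (Mkk6) and 2629 (Nanog), and replicate 2 alone 2084 (Glis1), 976 (Jdp2), 1 (Mkk6) and 28 (Nanog). With the other 6 dropouts as the reference the counts were 4833 (Esrrb), 155 (Kdm2b), 879 (Mkk6) and 222 (Nanog). With only the arms compared they were 1807 (Glis1), 0 (Kdm2b), 2 (Mkk6) and 16 (Nanog). Days 3 to 7 alone gave 0 (Kdm2b) and 413 (Nanog). No filter gave 12 (Kdm2b), 53 (Mkk6) and 305 (Nanog), and DESeq2 10, 235 and 382. The position with the Y'F lines at 1 was 0.488 for 7F, 0.539 without Kdm2b and 0.413 without Mkk6. Of 92 list calls 1 was left with an estimated correlation. The cause was not tested unless fewer samples are named. For TTF (2 lines, 2.77 to 3.67 M counts) 26 of 100 simulated 2-fold and 79 of 100 4-fold changes were recovered; depth was not tested as a cause.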

Other observations

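Pou5f1, a core pluripotency factor, was 46.3 CPM in the GFP library of day 0, which has 1.9 M counts, and at most 0.271 in the other GFP libraries. In the libraries labelled complete 7F it was 272 and 253 CPM on day 5 and 103 and 125 on day 7, against 913 to 977 in the iPSC lines made with 7F. The endothelial gene Cdh5 was 22.3 and 25.3 CPM in the libraries labelled complete 7F on day 7 and at most 0.235 in the 7F iPSC lines.

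Without Jdp2 the hormone gene Avp peaked at 230 CPM on day 3 and was 58.4 on day 5, where no library labelled complete 7F exceeded 2.53, and Pyy was 90.2, 126, 143 and 32.8 CPM on days 1, 3, 5 and 7. Without Glis1, Sox2 stayed between 1.42 and 11.5 CPM on the 5 days. Rhox5, an X-linked homeobox gene, was 246 CPM in the Y'F line 4 made from MEFs and 14 to 35.9 in the other lines of that group. No explanation was tested for these values.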
